A study of Yucca flaccida with 12 samples.

How the data were processed

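RNA was taken from the edge and the centre of in vitro leaves of variegated and unvariegated Yucca flaccida 'Golden Sword', with 3 libraries in each of the 4 groups. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, fragmented and copied into complementary DNA with random hexamers; no strand-marking step is described. Groups and replicate numbers were taken from the sample titles. All 12 libraries were used, and every column of the tables matched 1 library.

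The authors deposited a table of expected counts and a table of FPKM values for 185746 genes, each a cluster of assembled transcripts. Per the submitters' processing notes, CASAVA 1.8, RSEM and Bowtie2 were used; the versions of RSEM and Bowtie2, the assembler, the clustering and the reference assembly were not given in the sources used here. The deposited expected counts were not whole in 21.3% of values, and RSEM shares reads that match several transcripts among them. Genes that share sequence, such as allelic or paralogous clusters, are therefore uncertain as separate units. The deposited FPKM values divide the estimated counts by gene length and library total. For 579 gene and library combinations a 0 in either table stood against a value above 0 in the other. The identifiers were not paired with gene names and no reference was used, so gene lists for photosynthesis, chlorophyll, carotenoids, plastid biogenesis, stress, cell cycle, cell types and microbes that had been fixed before the data were examined were not applied, and no gene list was tested. The first number of an identifier was read as an assembly group; the largest of 62768 groups held 103846 genes and 97.8% of the counts.

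Expected counts were rounded to whole numbers before testing. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 59225 genes. The main test was edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling, estimateDisp, robust glmQLFit and glmQLFTest, with all 12 libraries in a single fit and Benjamini-Hochberg adjusted p below 0.05 as the threshold. The contrasts were VC against VE, UC against UE, VC against UC, VE against UE and the difference of the zone differences. Standard errors were obtained as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. This can understate the error where a group has almost no counts. No standard error is therefore given in contrasts with VC for Cluster-20123.85164 and Cluster-20123.13120, which had 13 and 3 counts over the VC libraries. CPM values use TMM-scaled library sizes. The comparisons, the main test, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named the 2 genes with the highest and the 2 with the lowest log2 fold change in VC against VE among those with adjusted p below 0.05, a mean of at least 10 CPM and all 3 libraries of one group above all 3 of the other.

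Principal components were computed from log2 CPM (prior count 2) of the 1000 most variable genes. Library measures were compared by two-sided exact permutation tests, and the set of the 100 most abundant genes with camera, once with a preset correlation of 0.01 and once with an estimated one. Counting intervals are at the 95% level, and both they and the floor of 3 counts cover counting error only. Effective gene lengths were derived per library from the ratio of expected count to FPKM over 13393 genes. Within groups, the chi-square per degree of freedom between replicates was 10.7 to 38.2, so no pair of libraries agreed within sampling noise.

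The edgeR fit was tested on simulated counts of 59225 genes. For VC against VE it recovered 4% of 2-fold, 48% of 4-fold, 70% of 8-fold and 80% of 16-fold changes, 50 genes each, with 5 false calls. For VC against UC it recovered 6%, 42%, 66% and 80% at the same folds, with 3 false calls. At total counts of 13139086 to 20306020 per library and 3 libraries per group, most simulated 2-fold changes thus stayed below the threshold. Few genes were changed in the simulation, which makes the adjusted threshold stricter than where many genes are called. In VC against UC, 2066 of the 3019 genes called had an absolute log2 fold change of at least 1, and the rest were below 2-fold. The simulated rates therefore do not carry over to the real comparisons.

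Alternatives were RLE size factors, library totals only, no low-count filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-trend on log2 of the deposited FPKM plus 1 or plus 0.1, a replicate block, only the 6 libraries compared, a log2 fold change of at least 1, and each library left out in turn. Removal of the trend with gene length and the omission of VE1 and UE1 together were added after the data were seen, as was limma-trend on log2 CPM. With the last, the interaction was also tested against 99 rearrangements of the residuals of an additive fit of zone and phenotype. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.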

Results

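Yucca flaccida 'Golden Sword' is an ornamental monocot cultivar whose leaves can be variegated, that is, marked by zones of different colour. Messenger RNA was sequenced from the edge and the centre of in vitro leaves of variegated and unvariegated plants, at the stage of the second youngest leaf. The 12 libraries fell into 4 groups of 3: variegated edge (VE), variegated centre (VC), unvariegated edge (UE) and unvariegated centre (UC). The labels do not say which zone was pale. They also do not say whether the 3 libraries of a group came from separate plants, so p-values here measure only the spread between these samples, which may be technical. Total estimated counts per library lay between 13139086 and 20306020, with means of 17403423 ± 442808 in VE, 16227542 ± 2282055 in VC, 16615197 ± 1384894 in UE and 16176001 ± 3706399 in UC (SD, n = 3 each). Of 185746 genes, here clusters of assembled transcripts, 59225 were abundant enough to test and held 98.9% of the counts. The files do not pair the gene identifiers with gene names, so genes are described below by their level and the groups in which they differed.

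Variegated and unvariegated libraries separated on the first principal component, which held 32.6% of the variance of the 1000 most variable genes. Variegated libraries lay between -86.7 and -25.7 on it and unvariegated libraries between 31.2 and 50, with VE replicate 1 at the low extreme. The second component, with 11.3% of the variance, placed VE above VC but did not separate UE from UC: UE1, UE3 and UC1 had positive scores and UE2, UC2 and UC3 negative ones. The number of detected genes was close in all groups, at 104220 ± 1709 in VE, 107419 ± 9452 in VC, 105857 ± 7873 in UE and 107342 ± 4367 in UC (SD, n = 3). Neither this number nor the total count differed between phenotypes beyond the spread of the libraries (two-sided exact permutation p of 0.831 and 0.736, 6 against 6).

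**Figure D1:**
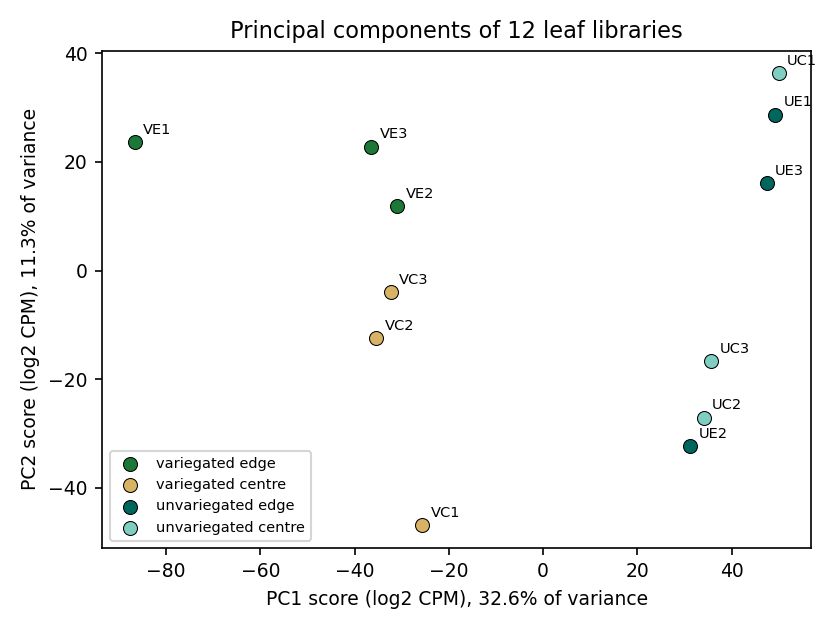
Scores of the 12 libraries on the first and second principal components of log2 CPM, with 1 point per library and colour for the group. Variegated libraries sit at or below -25.7 on the first component and unvariegated libraries at or above 31.2, while the edge and centre of unvariegated leaves are mixed on the second.

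Abundant transcripts took up a larger share of the RNA at the edge than in the centre of the variegated libraries, though the tests did not pass their thresholds. The 100 most abundant genes held 30.9% ± 0.518 of the counts in VE, 22.6% ± 1.79 in VC, 25.9% ± 1.45 in UE and 24.2% ± 1.22 in UC (SD, n = 3). Over both phenotypes the share was 23.43% in centres and 28.42% in edges (two-sided exact permutation p = 0.00433, 6 against 6; Benjamini-Hochberg adjusted 0.0779 over 18 tests of library measures), which did not pass 0.05 after adjustment. In unvariegated leaves alone the difference was -1.7 points (exact permutation p = 0.2, adjusted 0.9). Both the VC against VE and the VE against UE differences, -8.27 and 4.99 percentage points, had an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. As a fixed set, the 100 genes most abundant over all libraries had a median log2 fold change of -0.65 in VC against VE and 0.55 in VE against UE. These medians were -0.34 and 0.28 when only library totals were used for scaling. Camera with a preset correlation of 0.01 placed the set below the other genes in VC against VE (adjusted p = 6e-23) and above them in VE against UE (adjusted p = 2.97e-07). It also placed the set lower in UC against UE (adjusted p = 0.000254) and in the interaction (adjusted p = 6.85e-10), but not in VC against UC (adjusted p = 0.586). None of the 4 calls held with an estimated correlation (adjusted p = 0.0895, 0.268, 0.379 and 0.246 in the same order).

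Within variegated leaves, the comparison of centre with edge asked which transcripts accompany the zones of the variegated blade. In the centre 227 genes were higher and 338 lower than at the edge, 565 in all, with median log2 changes of 1.26 and -1.35. Large decreases outnumbered large increases: 61 genes were lower by at least 3 on the log2 scale and 12 higher. Among the 13784 genes with a mean of at least 10 CPM, the count scaled to library size, 134 were higher and 225 lower, and 19 of these fell by at least 3 against 0 that rose by as much. Cluster-20123.55721 rose from 79.4 ± 13.6 CPM in VE to 570 ± 35.1 CPM in VC, and Cluster-20123.55719 from 23.5 ± 6.07 to 160 ± 23.7 CPM (SD, n = 3). Cluster-20123.85164 fell from 80.3 ± 14 CPM in VE to 0.228 ± 0.162 CPM in VC. From counts pooled over the 3 libraries of each group and divided by their scaled library sizes, the ratio of VE to VC was 318, with a 95% counting interval of 186 to 598. Cluster-20123.13120 had 1663 counts over the 3 VE libraries and 3 over the 3 VC libraries, a ratio of 656 when pooled and scaled in the same way (95% counting interval 224 to 3180). Such intervals cover counting error only, and the VE libraries of this last gene ranged from 4.29 to 90.4 CPM.

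The genes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold changes were 2.85 (SE 0.34, adjusted p = 0.00476) for Cluster-20123.55721 and 2.76 (SE 0.25, adjusted p = 0.000793) for Cluster-20123.55719. They were -8.29 (adjusted p = 5.49e-07) for Cluster-20123.85164 and -9.18 (adjusted p = 0.0407) for Cluster-20123.13120 in the same edgeR test. Cluster-20123.55721 and Cluster-20123.55719 have nearby identifiers, and no sequences were used here, so reads shared between them could not be ruled out. The call of Cluster-20123.13120 was lost without VE1, VE2, VC1, VC2, VC3 or UC2. Adjusted p from edgeR's quasi-likelihood test was then 0.124, 0.0862, 0.102, 0.203, 0.143 and 0.059 (range over all alternatives 0.000287 to 0.206). This call was also lost with no filter and with the replicate block (adjusted p = 0.0535 in the same test). So it was with only the 6 libraries compared and without VE1 and UE1 together. The count of 565 was 205 without VE1, 115 without VE2, 193 without VE3, 87 without VC2, 224 without VC3 and 368 without UC2, and the direction of the calls depended on scaling: with library totals only, which moved the median of all genes by 0.33, 1815 genes were higher and 271 lower, and deposited FPKM gave 1486 higher and 282 lower, with a median shift of 0.21.

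**Figure D2:**
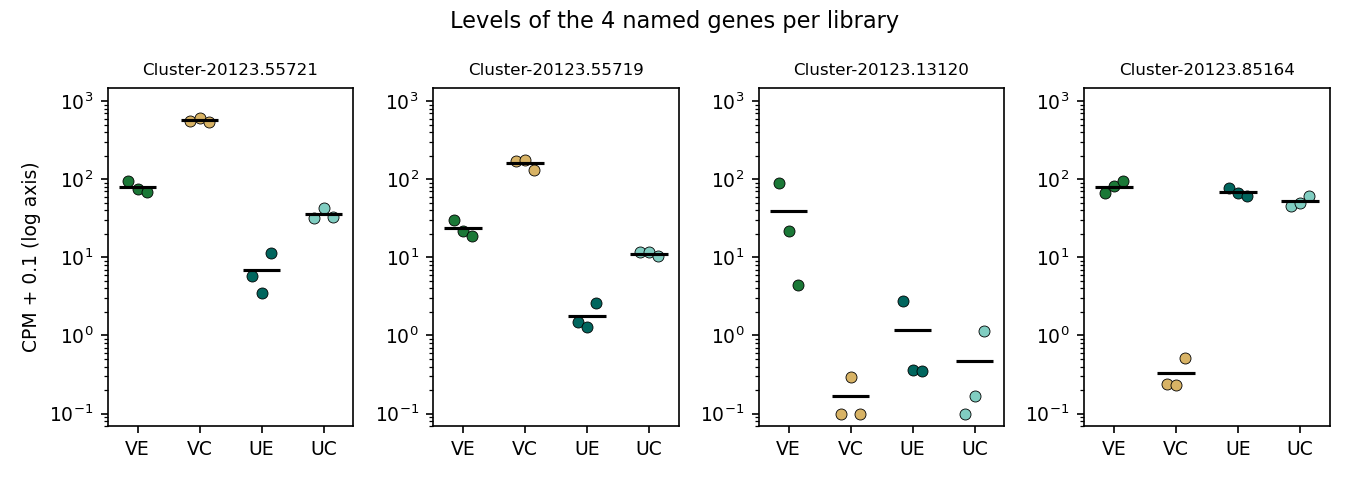
Level of each named gene in every library, as CPM plus 0.1 on a log axis, with 1 point per library and a line at the mean of the 3 libraries of the group. Cluster-20123.55721 and Cluster-20123.55719 are highest in VC (570 and 160 CPM), and Cluster-20123.85164 is at 0.228 CPM in VC against 52 CPM or more in the other groups.

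A set of 14 genes, picked after their values were seen, was nearly missing from the variegated centre alone. In each of the 3 VC libraries these genes were below 0.1 times their lowest level in the other 9 libraries, and their median level was 0.363 CPM in VC against 28.9 CPM elsewhere. Cluster-20123.85164 was one of them. The rule that picked them sets their calls against VE and UC, where all 14 were lower. The rule also favours a negative interaction, so the 7 of the 14 called there are not separate support. In VE against UE 1 was called. Their median level in UE2 was 62.9 CPM, against 17.4 to 29.2 CPM in the other libraries of VE, UE and UC. The count was 24 without VC3 and 15 to 19 without any other library. Leaving out a library only loosens the rule, so the count could not fall below 14.

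**Figure D3:**
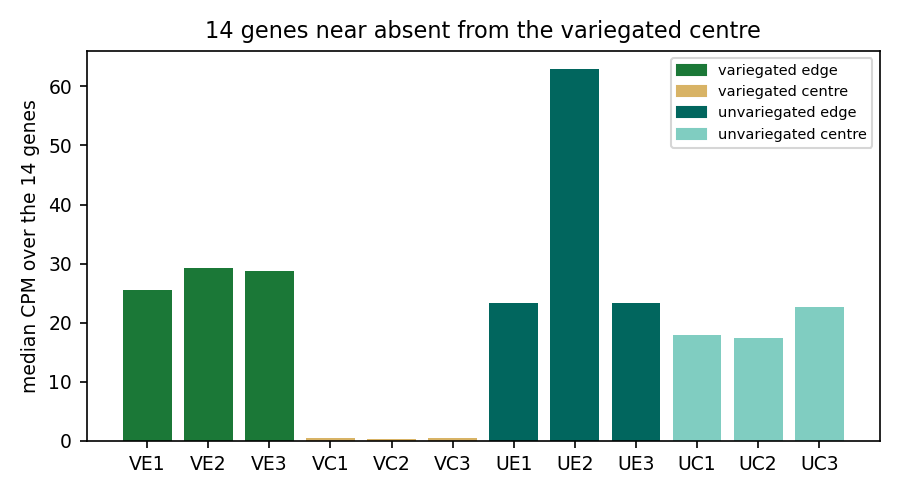
Median CPM over the 14 genes that were nearly missing from VC, with 1 bar per library and colour for the group. The VC bars are at 0.231 to 0.393 CPM and those of the other libraries at 17.4 to 62.9 CPM, the highest being UE2.

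The same zones of unvariegated leaves were compared as a reference for position in a leaf without variegation. Few differences were detected between centre and edge of unvariegated leaves: Cluster-20123.55719 alone passed the threshold, with 11.1 ± 0.796 CPM in UC and 1.69 ± 0.708 CPM in UE (SD, n = 3; log2 fold change 2.68, SE 0.28, adjusted p = 0.0384 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cluster-20123.55721 had 36.1 ± 6.27 CPM in UC and 6.74 ± 4.01 CPM in UE, but its adjusted p in the same edgeR test was 0.266. It passed in DESeq2 (log2 fold change 2.41, adjusted p = 1.49e-09) and in edgeR without UE3 (3, adjusted p = 0.00903), with a range of up to 0.906 over all alternatives. Cluster-20123.85164 stood at 52 ± 7.85 CPM in UC and 69.1 ± 8.58 CPM in UE (log2 fold change -0.41, SE 0.21, adjusted p = 0.966 in edgeR). At an unadjusted p below 0.05 there were 3091 genes, 5.22% of those tested, and DESeq2 called 108. The call of Cluster-20123.55719 was lost without VE2, VE3, VC1, VC2, VC3, UE1, UE2, UC1 or UC2, leaving 0 genes, or in the case of UC1 a single different gene, whereas 2 genes were called without UE3 and 7 without UC3. The call was also lost with the replicate block (adjusted p = 0.3 in the edgeR test) and when only the 6 unvariegated libraries were fitted. The same held when the trend with gene length was removed and when VE1 and UE1 were both left out. Each of these settings gave 0 genes, while the gene's log2 fold change stayed at 2.67, 2.69, 2.57 and 2.55 in this order. Separately, estimated effective gene lengths in UC1, UC2 and UC3 were offset by 24.9, 22.5 and 9.4 bases from those of the remaining libraries, which lay within -2 and 3.2 bases, and genes with effective lengths under 300 bases had a median log2 fold change of 0.23 in UC against UE.

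The phenotypes were compared in the leaf centre, asking which transcripts differ between variegated and unvariegated plants in the same zone. In VC 1582 genes were higher and 1437 lower than in UC, 3019 in all, with median log2 changes of 1.19 and -1.39. By at least 3 on the log2 scale, 222 were higher and 169 lower. Among genes with a mean of at least 10 CPM, 1001 were higher and 630 lower. Cluster-20123.55721 and Cluster-20123.55719 were again higher, by 3.98 (SE 0.35, adjusted p = 0.000485) and 3.85 (SE 0.26, adjusted p = 5.74e-05) on the log2 scale in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cluster-20123.85164 was lower, at -7.67 (adjusted p = 1.63e-06, same edgeR test). Cluster-20123.13120 did not pass the test, with 0.0661 ± 0.115 CPM in VC and 0.371 ± 0.583 CPM in UC. Short genes moved with the UC libraries: under 300 bases the median log2 fold change was -0.33, with 103 genes higher and 354 lower, against 0.02 over 1000 bases, with 826 higher and 515 lower. The count of 3019 was 908 without VC1, 700 without VC2, 4609 without VC3, 1380 without UC1, 1153 without UC2 and 1624 without UC3.

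At the leaf edge, 1970 genes were higher and 1150 lower in variegated than in unvariegated plants, 3120 in all, with median log2 changes of 1.54 and -1.5. Large increases were more frequent here: 307 genes were higher and 186 lower by at least 3 on the log2 scale, and 71 of the 307 belong to a set seen in the variegated libraries only, as do 25 of the 222 in the centre. Of the 100 most abundant genes, 28 were called higher and 4 lower in VE, while in the centre 3 were higher and 13 lower. Cluster-20123.55721 and Cluster-20123.55719 were higher in VE by 3.54 (SE 0.35, adjusted p = 0.00177) and 3.77 (SE 0.28, adjusted p = 0.000248) on the log2 scale in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cluster-20123.13120 was higher by 5.19 (SE 1.29, adjusted p = 0.043, same edgeR test), a call lost without VE1, VE2, VC2, UE1, UE2, UE3 or UC2, and also with no filter, with only the 6 libraries compared, with FPKM plus 0.1 and without VE1 and UE1 together. Cluster-20123.85164 had 80.3 ± 14 CPM in VE and 69.1 ± 8.58 CPM in UE (adjusted p = 0.634, edgeR). VE replicate 1 stood apart from the rest: 484 genes had at least 100 counts over the variegated libraries and at most 3 over the unvariegated ones, 69.5% of their counts were in VE1, and 71 of them were called higher in VE and 25 in VC, all by at least 3 on the log2 scale.

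The count of 3120 at the edge was 948 without VE1, 1065 without VE2, 2044 without VC2, 1061 without UE1, 870 without UE3 and 120 with VE1 and UE1 both left out. Its direction depended on scaling: with library totals only, which moved the median of all genes by -0.32, 1402 genes were higher and 2847 lower, and deposited FPKM gave 1655 higher and 2850 lower, with a median shift of -0.2.

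**Figure D4:**
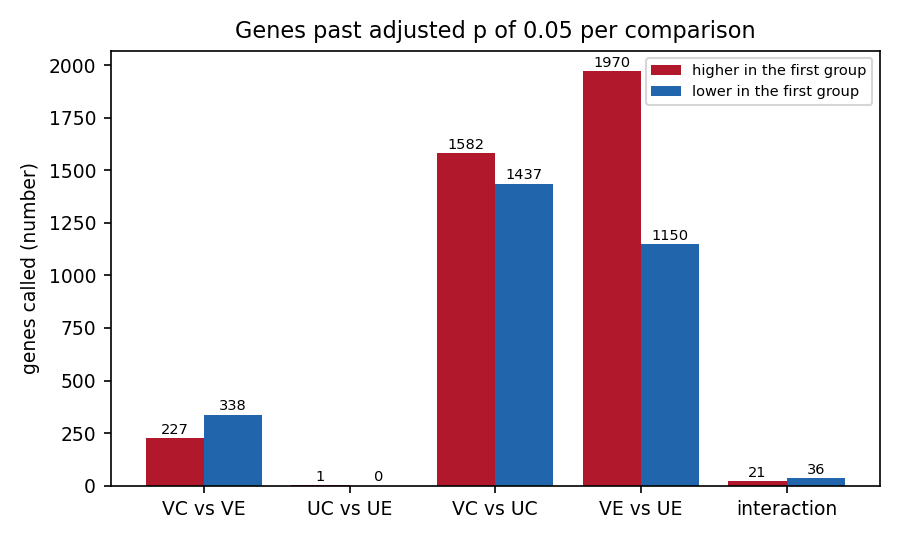
Number of genes past an adjusted p of 0.05 in each comparison, with 1 bar for genes higher and 1 for genes lower in the first group named; for the interaction, higher means a more positive centre-edge difference in variegated leaves. The phenotype comparisons hold 3019 and 3120 genes, VC against VE 565 and UC against UE 1; the split between higher and lower in VC against VE, in VE against UE and in the interaction turned over with library totals as the only scaling.

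Differences between the phenotypes mostly had the same sign in both zones. Of the genes called in the centre, 87.6% had the same sign at the edge, and of those called at the edge 90.8% had the same sign in the centre. Both comparisons called 1106 genes, 644 of them higher and 445 lower in variegated leaves of either zone and 17 in opposite directions. Independent lists of these sizes would share 52.6 and 27.9. That reference is likely too low, since both lists come from 1 fit and abundant genes were called more often. At a mean of at least 10 CPM, 11.8% were called in the centre and 12.6% at the edge, against 0.834% and 0.887% under 1 CPM. Across genes, which are not independent replicates, the log2 fold changes of the phenotypes in centre and edge had a Pearson correlation of 0.48, or 0.77 for genes with a mean of at least 10 CPM, and no library enters both comparisons. Zone differences in variegated and unvariegated leaves had a correlation of 0.03 across genes, or 0.12 for genes with a mean of at least 10 CPM. Of the 565 genes called in VC against VE, 49.4% had the same sign in UC against UE, where the median log2 changes of those higher and lower in VC were -0.08 and -0.11. Only 1 gene was called in UC against UE. Noise in those estimates would weaken the correlation and draw the sign share toward an even split. Neither of these values shows by itself that zone effects are not shared.

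Genes that differed between the zones of variegated leaves also recurred in the comparison of centres. Of them, 112 were higher in VC than in both VE and UC and 162 lower than in both. Independent lists would share 6.06 and 8.2, a reference that again takes no account of abundance. Both comparisons use the VC libraries. In 10 simulations with no effect 0 genes were called, so the simulated overlap of 0 does not measure what the shared libraries add. The correlation of the log2 fold changes was 0.22 across genes against 0.49 in the simulations, and their covariance 0.307 against 0.384. The 3 VC libraries are too few to be split between the comparisons, so part of the excess overlap may come from the shared libraries.

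Whether the centre-edge difference itself differed between phenotypes was tested as an interaction. It did for 57 genes, 21 with a more positive and 36 with a more negative centre-edge difference in variegated leaves. The more positive calls depended on single libraries: they numbered 0 without VE2, UE3 or UC2 and 1 without VC2, UE1 or UC1. Their highest number with a library left out was 20, without UE2. Of the 57, 55 were also called in VC against VE, 50 in VC against UC and 25 in VE against UE. The difference of Cluster-20123.85164 was -7.88 (adjusted p = 6.51e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). For Cluster-20123.55721 and Cluster-20123.55719 the interaction was 0.44 and 0.08, with adjusted p of 0.861 and 0.989 in the same edgeR test. The count was 15 without VE1, 9 without VE2, 24 without VE3, 15 without VC2, 35 without VC3, 18 without UE1, 12 without UE3, 13 without UC1, 10 without UC2 and 35 without UC3. With library totals only, which moved the median of all genes by 0.21, 36 were more positive and 31 more negative, and deposited FPKM gave 61 and 33.

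The number of transcripts present in one phenotype and missing from the other depended on the rule. With at least 10 counts in each of the 6 libraries of one phenotype and 0 in the other 6, there were 8 genes, 7 of them in variegated plants. With at least 100 counts summed over the variegated libraries and 0 in the unvariegated ones there were 461, a rule set after the data were seen. Such genes rested largely on VE1: with up to 3 counts allowed in the unvariegated libraries there were 484, and 178 without VE1. The 10-count rule applied to centre against edge gave 0 genes. A count of 0 in a library allows up to 3 counts of its total, so low expression in the other phenotype was not detectable at this depth. Leaving out VC1 raised the number of 8 to 79 genes, 78 of them in variegated plants, and leaving out VC3 raised it to 13. Leaving out a library only loosens this rule, so the number could not fall.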

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

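The count of reads regained by neighbouring clusters and both rearrangements of the libraries for the interaction were set out before their own results were seen, the residual one after the 57 genes were known; the other tests in this part were chosen after.

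The centre-edge difference differed between the phenotypes, by a test of the difference itself, for 57 genes. When phenotype labels were permuted within each zone, 1 of 100 drawn arrangements, the real one, gave as many; the highest of the others gave 25. Mixing the phenotypes also removes their main effect, so this does not test the interaction alone. With the main effects kept, by rearranging the residuals of an additive fit, limma-trend called 93 genes, which include all 57. Of 100 arrangements 1, the real one, gave as many and the highest other gave 2. This argues against additive effects alone as the source of the limma-trend count only if the 12 libraries are independent and their residuals have equal spread. Equal spread was not established, since the chi-square per degree of freedom between replicates varied from 10.7 to 38.2. The labels do not settle whether the libraries are independent. The edgeR count of 57 ranged from 9 to 72 when each library was left out. It was 9 without VE2 and 35 or fewer without VE1, VE3, VC2, VC3, UE1, UE3, UC1, UC2 or UC3.

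The same test marked Cluster-20123.85164, whose centre-edge difference was lower in variegated leaves by a log2 value of -7.88. It belongs to the 14 genes nearly missing from VC. Of all 220 sets of 3 libraries, 2 had as many genes nearly missing from those 3 alone, VC itself and a set of unvariegated libraries with 19; the genes were picked after these counts were seen, so chance was not excluded. A shift in fragment length was argued against by effective lengths, which differed by 2.6 bases between VC and VE. Reads moved to a differently assembled copy cannot be told apart from loss: clusters numbered within 5 of a lost gene regained a median share of 0.196 of its CPM, with 3 of the 14 at 0.5 or more, which lies between the bounds set for and against it (at least 0.5 and below 0.1). Only gains of these clusters were summed, so unrelated rises add to the share. No share was computed for genes that were not lost, and close numbers need not mean shared sequence. In UE2 57.1% of the genes were raised at least 2-fold, against 1.42% of genes of similar level; this level had been seen beforehand and leaves a shared transcript source untested. A difference between the phenotypes in the leaf centre stays open.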

How the results depend on the processing

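Removing the gene-length trend, leaving out VE1 and UE1 together and limma-trend on log2 CPM were chosen after seeing the data; the other alternatives were planned. Unless stated, the cause of a change was not tested. In VC against VE, where 565 genes were called, library totals only gave 2086, no filter 956, DESeq2 2243, FPKM plus 1 1768 and FPKM plus 0.1 1764. Fewer libraries gave 136 (only the 6 compared), 124 (VE1 and UE1 left out) and 87 to 626 (each library left out). In UC against UE, where 1 gene was called, no filter gave 26, DESeq2 108 and FPKM 2 with either pseudocount, while fitting only the 6 libraries, removing the length trend and leaving out VE1 and UE1 each gave 0, and leaving out each library 0 to 7. In VC against UC, DESeq2 called 6467 genes, the 6 libraries alone 818, and leaving out each library 700 to 4609. In VE against UE, DESeq2 called 5989, leaving out VE1 and UE1 120, and leaving out each library 870 to 3931. The interaction gave 319 genes with no filter, 800 with DESeq2, 94 with FPKM plus 1, 93 with limma-trend on log2 CPM, 5 without VE1 and UE1, and 9 to 72 without each library. RLE size factors and the stricter filter kept all 5 counts within 1.5 times. Whether the replicate numbers pair the libraries is not given in the labels and was not settled by the values. Correlations of deviations between same-numbered libraries were 0.11, 0.02 and 0.13 for VC with VE and 0.1, 0.07 and -0.05 for UC with UE. They were below 0.02 in the phenotype comparisons, and 7 of 12 libraries correlated best with their own number. With the replicate block the counts were 644, 0, 2890, 3301 and 41.

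The correlation of zone effects across genes was 0 to 0.1 with each library left out. The correlation of phenotype effects was 0.43 by Spearman, 0.53 with the stricter filter, 0.58 with FPKM, and 0.4 to 0.45 with each library left out. Genes seen in one phenotype numbered 31 at 5 counts, 3 at 20 counts and 16 with up to 3 counts in the other phenotype. With each library left out they numbered 8 to 79, where the rule allows only a rise. The share of counts differed by -4.96 points between VC and VE for the 10 most abundant genes. In VC against VE, the named genes Cluster-20123.55721, Cluster-20123.55719 and Cluster-20123.85164 kept their call and direction under all 24 alternatives, and Cluster-20123.13120 kept its direction. Reversals fell on values that had not passed the test: the interaction of Cluster-20123.55721 was -0.15 without UE3 and up to 0.75 without other libraries; that of Cluster-20123.55719 was -0.07 without VE3 and -0.34 without UE3, and up to 0.31 without VE1; Cluster-20123.13120 was at 0.65 in UC against UE without UE1 (lowest -4.75, without UC3) and 0.59 without VE1 and UE1, and at 0.76 in VC against UC without UC3 (lowest -5.8, without VC2); Cluster-20123.85164 was at -0.05 in VE against UE with library totals only and -0.07 with FPKM at either pseudocount. Simulated 2-fold changes were mostly missed at this depth and number of libraries when few genes were changed. The gene list tests, planned with camera at a preset correlation of 0.01 and with an estimated correlation beside it, were not run because the identifiers carry no names. The number of genes nearly missing from VC was 27 at a threshold of 0.2 and 7 at 0.05 in place of 0.1, and of those nearly missing from UE1, UE3 and UC1 24 and 18; these thresholds were also chosen after seeing the data.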

Other observations

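The tests of the gene sets in this part were chosen after the sets were seen; the other splits of the libraries in the last paragraph were planned, except for the genes seen in one phenotype.

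A group of 19 genes was nearly missing from UE1, UE3 and UC1, with a median of 0.0627 CPM against 33.9 CPM in the other 9 libraries, a set that lies within the unvariegated libraries and spans both zones. No comparison of the report called any of them. Of the 220 sets of 3 libraries 1, this one, had as many such genes, and the highest other set had 14; the set was picked as the highest, so this does not exclude chance. The number was 29 without UC3, and leaving out a library could only raise it. Phenotype cannot be the whole cause, since UE2, UC2 and UC3 held these genes at median levels of 76.7, 29.4 and 11.4 CPM, with a median ratio of 1.06 to the variegated libraries, although presence there was part of the rule that picked them. The genes rose and fell together over the 9 libraries, with a median pairwise correlation of 0.82 against 0.091 at the 95th percentile of random sets, which is consistent with a single RNA source; 17 of the 19 lay in the largest assembly group, and the nature of the source was not tested.

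The 484 genes seen in the variegated libraries only stood against 65 seen in the unvariegated libraries only. Among all splits of the libraries into 6 and 6, 1, the real one, gave as many, and the highest other gave 344; the thresholds were set after the genes were seen, so chance was not excluded. Without VE1 there were 178 genes, against 70 in the unvariegated libraries. Greater depth was argued against by a ratio of mean total counts of 1.03. RNA of another organism in the variegated cultures may contribute, since 68% of the genes lay outside the largest assembly group, 51.1% without VE1. The share among tested genes was 14.1%, but only 299 of the 484 genes were tested. Of all 185746 genes, 103846 lay in that group, so the tested genes are not a like reference. Genes seen in the unvariegated libraries only were outside it in 46.2% of cases, so these shares do not settle the question. A difference in genotype or expression between the phenotypes stays open and was not tested.

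Genes with at least 20 counts in 1 library and 0 in the other 11 numbered 264 in UE1 and 119 in VE1, against 7 to 25 in each of the other libraries. Of these, 90.5% in UE1 and 80.7% in VE1 lay outside the largest assembly group, against 0% to 46.7% in the others. This trait was thus not limited to the variegated libraries.

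For the 8 genes seen in one phenotype, 1 of all splits of the libraries into 6 and 6, the real one, gave as many. The highest other split gave 3. That test was chosen after the genes were seen, and whether the libraries are independent is not settled, so chance was not excluded. The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 565 genes in VC against VE and the highest other 1. In VC against UC these numbers were 3019 and 1, and in VE against UE 3120 and 1. In UC against UE the real split gave 1 gene, 3 of the 10 splits gave as many, and the split of UE1, UE3 and UC1 from UE2, UC2 and UC3 gave 27. The same grouping was seen on the second principal component of these libraries. Its count is therefore not separate support for a structure other than zone.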
